A study of Mus musculus with 8 samples.

How the data were processed

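Polyadenylated RNA of mouse liver was measured in 8 libraries, 4 from hosts of Colo201 and 4 from hosts of HCT116 xenografts, with 2 labelled male and 2 labelled female in each line. Per the labels' protocols, livers were kept in a stabilising solution, total RNA was extracted with TRIzol, and libraries were made with a stranded TruSeq mRNA kit. Per the submitters' processing notes, HISAT2 and StringTie were used with GRCm38 (mm10); their versions, the annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes may be joined. The deposited table of estimated counts holds whole numbers per gene, which edgeR took as they stand. How they were derived from reads is not given. Among values of 1 to 16, 43.9 to 45.0% were multiples of 4, where 25% would be by an even spread, and over 6969 genes the ratio of count to FPKM was constant between libraries within a gene (SD 0.0013 on the log2 scale). The authors' FPKM table, rounded, is therefore not independent of the counts and served only in alternatives.

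The totals were 62430779, 65457482, 64807244 and 61762914 estimated counts in Colo201 2L, 2R, 4L and 4R and 61352839, 63298489, 63597281 and 61347603 in HCT116 1L, 1R, 3L and 3R. A fragment was taken as 4 counts, or 0.0611 to 0.0652 CPM, for the floor of a gene at 0; floors cover counting error only. Both tables list 55401 gene identifiers, of which 55141 matched a symbol in GENCODE vM21, an annotation of GRCm38 that may not be the one the authors used. The 260 without a symbol held 0.0216 to 0.0343% of the counts. No libraries were duplicates, with a chi-square per gene of at least 15.62 over the 28 pairs of libraries. The 4 pairs that share a title number had the lowest values, 15.62 to 31.6 against 39.85 to 125.21 in the other 24 pairs. They are also the only pairs that share both line and sex label, so these values cannot tell whether L and R depend on each other. All columns of per-sample values were used.

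Counts were scaled by TMM and filtered by filterByExpr, and 17669 genes were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest). The comparison of lines had sex label as a covariate and the comparison of sex labels had line; both left 5 residual degrees of freedom. Comparisons within a sex label and the interaction, the difference between lines in libraries labelled female minus that in libraries labelled male, came from a fit with a mean for each of the 4 combinations. P-values were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. Standard errors were taken from the log2 fold change and its F statistic. CPM are given as mean ± SD over libraries. The 34 gene lists, the comparisons, the tests and the alternatives other than those said to be added were fixed before the data were examined, and the 33 with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01, with camera and an estimated correlation, and with fry, adjusted over the lists; counts of members are given over all genes and adjusted over the list alone. No replicate numbers are shared between the lines, so no pairing was fitted.

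The genes named were chosen by a rule set at the same time: 13 genes of bile acid control and FGF19 signalling whatever their result; the 10 largest rises and 10 largest falls among passing genes with at least 1 CPM on average, full separation of the lines and a proper name; up to 4 members of each list with the smallest p; up to 5 genes per direction of the interaction and of the comparison of sex labels; and the sex chromosome genes. Other members of a list are named where they passed or where they belong to the same step. The alternatives were other scalings, DESeq2 1.42.0 and limma voom, other filters, stricter thresholds, limma on log2 FPKM with a pseudocount of 1 or 0.1, the 20 most abundant genes left out, other covariates, and each library left out in turn. Counts divided by 4 and libraries summed by title number were added after the data were seen.

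The fits were tested on simulated data with 200 changed genes at the measured means, library sizes and spread, with libraries drawn independently. Any dependence between libraries of a title number was not simulated, so the rates hold only without it. For the comparison of lines edgeR recovered 68% of 2-fold and 99% of 4-fold changes among 17097 genes with 6.2% false calls, against 22.3% for DESeq2. For a change placed in libraries labelled female only, the contrast within that label recovered 15% and 77% and the interaction 0% and 42%. A list moved by 0.6 on the log2 scale, that of cholesterol synthesis and uptake, was recovered by all 3 list tests, with 0 other lists called. Genes were drawn independently of each other, whereas in the data camera estimated a correlation of 0.496 between members of this list. The simulation therefore gives no rate of false calls for the lists as measured.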

Results

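Liver RNA was sequenced from NOD scid gamma mice, an immunodeficient strain, that carried subcutaneous xenografts of a human colorectal cancer cell line. The 8 liver libraries fell into 2 groups of 4. The first group came from hosts of Colo201, which the series gives as the line with high FGF19, and the second from hosts of HCT116, given as the line with low FGF19. FGF19 is a hormone of the intestine that signals to hepatocytes through FGFR4 and its co-receptor Klb and represses bile acid synthesis, and the series asks how tumour-derived FGF19 alters the liver transcriptome of the host. No library came from a host without a tumour, and FGF19 was not varied within a line. Differences between the lines therefore cannot be assigned to FGF19 apart from other differences between the tumours. Each line had 2 libraries labelled male and 2 labelled female. The libraries held 61347603 to 65457482 estimated counts, with a count above 0 for 19370 to 20272 genes, so depth was nearly even, and Alb alone took 7.51 to 12.02% of the counts. In all 8 libraries the expression of X- and Y-linked genes was opposite to the sex label, so sex is written here only as labelled. The titles combine a number with L or R, each number belongs to 1 line and 1 sex label, and the labels do not say whether L and R of a number were separate animals; p-values therefore measure the spread between these libraries, which may be technical.

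The main comparison asked which liver genes differed between hosts of Colo201 and hosts of HCT116. Cyp7a1, the rate-limiting enzyme of the classical bile acid pathway, was almost lost in hosts of Colo201, at 1.24 ± 1.58 CPM against 206 ± 20.6 CPM in hosts of HCT116 (SD, n = 4 each), a log2 fold change of -7.59 (SE 0.76, adjusted p = 0.00381, edgeR quasi-likelihood test). Cyp8b1, the sterol 12-alpha-hydroxylase that sets the share of cholic acid, fell by 2.33 on the log2 scale (SE 0.25, adjusted p = 0.00469), from 183 ± 86.7 to 36.0 ± 17.1 CPM. Cyp27a1, which opens the alternative pathway, fell by 1.14 (SE 0.14, adjusted p = 0.00666), while Cyp7b1, the next enzyme of that pathway, stood at a log2 fold change of -0.07 (adjusted p = 0.923). In the other direction Akr1c18, a 20-alpha-hydroxysteroid dehydrogenase, rose by 7.27 (SE 0.53, adjusted p = 0.000932) to 21.7 ± 13.1 CPM from 0.153 ± 0.22 CPM. In GRCm38 coordinates Cyp7a1 (ENSMUSG00000028240) lies on chromosome 4 from 6265612 to 6275633, Cyp8b1 (ENSMUSG00000050445) on chromosome 9 from 121914356 to 121916305, and Akr1c18 (ENSMUSG00000021214) on chromosome 13 from 4132615 to 4150654.

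**Figure D1:**
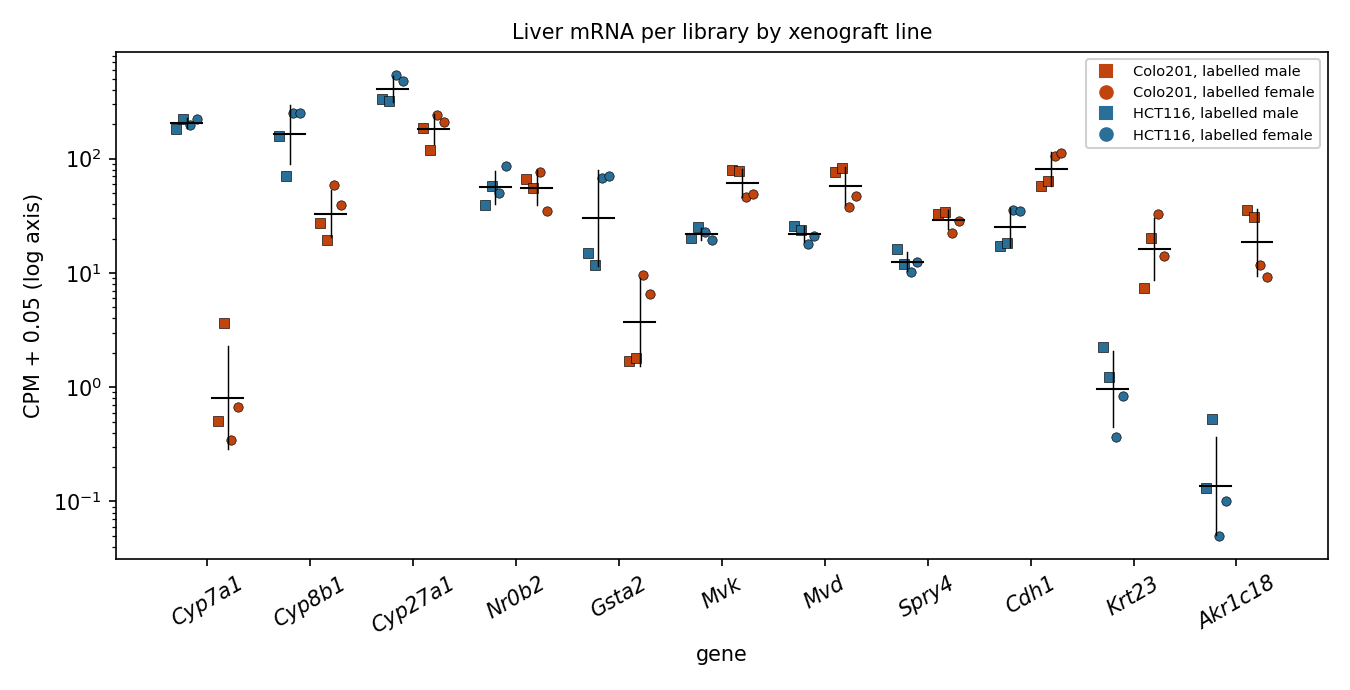
Counts scaled to library size (CPM, plus 0.05, log axis) of 11 genes in the 8 libraries, HCT116 at left and Colo201 at right of each gene, with squares for libraries labelled male and circles for those labelled female; horizontal lines are means and vertical lines ± 1 SD of log2 values. Cyp7a1 lies at 181 to 223 CPM in the 4 HCT116 libraries and at 0.297 to 3.61 CPM in the 4 Colo201 libraries.

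Of 17669 genes tested with edgeR, 439 were higher and 406 lower in hosts of Colo201 at an adjusted p under 0.05, and 99 and 113 of them changed by at least 2-fold. The 4 libraries of one line lay entirely above those of the other for 670 of the 845 genes; over all tested genes this held for 12.32%, where chance gives 2.86% if the 8 libraries are independent, and more if those of a title number are not. Changes were ranked only among passing genes with at least 1 CPM on average, full separation of the lines and a proper name. After Cyp7a1 the largest falls among these were those of Pcdhgb2 (-4.17), Csad (-3.56), Adgrg2 (-3.49), Gsta2 (-3.05), Amer2 (-3.01), Tgif2 (-2.63), Cyp8b1, Fam25c (-2.21) and Plin4 (-2.14), in log2 units. Csad, an enzyme of taurine synthesis, went from 204 ± 160 to 12.8 ± 2.86 CPM. Within the same limits the largest rises after Akr1c18 were those of Miox (4.31), Krt23 (4.13), Ifi27l2b (3.09), Fam198a (2.37), Atp2b2 (2.24), Drc1 (2.18), Smpd3 (2.11), Wnk4 (1.84) and Apoa4 (1.79). Apoa4, an apolipoprotein of intestine and liver, reached 619 ± 459 CPM against 171 ± 80.6 CPM. Akr1c18, Gsta2 and Pcdhgb2 have close paralogs or shared exons with which the counting may have split reads. When the libraries of each title number were summed, leaving 4 libraries and 1 residual degree of freedom, edgeR called 0 genes higher and 3 lower (Cyp8b1, Gsta2 and Serpina3c, the last named after its values were seen), with 1719 and 1761 at an unadjusted p under 0.05. Leaving out any of the 8 libraries lowered the counts, to between 86 higher and 89 lower without HCT116 3L and 267 higher and 283 lower without Colo201 4R.

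Of 18 tested enzymes of bile acid synthesis 5 fell (Cyp7a1, Cyp8b1, Cyp27a1, Baat, Slc27a5), 1 rose (Hsd3b7, log2 fold change 0.84) and 12 did not pass; adjusted over the list alone, 9 fell and 1 rose. Slc27a5, which activates bile acids to their CoA thioesters, fell by 0.40, and Baat, which conjugates these with taurine or glycine, by 0.55. The list as a whole was lower by camera with its preset correlation (adjusted p = 0.000987; adjusted p = 0.633 with an estimated correlation) and by fry (adjusted p = 0.0105). Of 16 bile acid and lipid transporters 2 fell, the uptake carrier Slco1b2 (-0.50) and the canalicular exporter Abcc2 (-0.42), 3 adjusted over the list alone. Abcb11, the bile salt export pump, had a log2 fold change of 0.06 (adjusted p = 0.729).

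The list of FGF19 receptor components and bile acid nuclear receptors had 19 tested members, of which 4 fell and 1 rose, or 6 and 2 adjusted over the list alone. Nr1i3 (CAR) fell by 1.28 (SE 0.17, adjusted p = 0.0093), Nr1i2 (PXR) by 0.52 and Nr1h4 (FXR) by 0.46, while Fgfr3 fell by 0.70 and Fgfr2 rose by 0.70. The receptor Fgfr4 (-0.08, adjusted p = 0.593), its co-receptor Klb (0.29, adjusted p = 0.233) and the FXR target Nr0b2 (0.01, adjusted p = 0.984) did not pass. Fry gave an adjusted p of 0.00256 for a shift downwards, and camera 0.0516 with its preset and 0.633 with its estimated correlation.

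Among 21 targets and feedback regulators of ERK signalling, 2 rose, Spry4 (1.22, SE 0.14, adjusted p = 0.0049) and Etv5 (1.09, adjusted p = 0.0325), and 6 rose and 1 fell adjusted over the list alone. Spry4 stood at 29.5 ± 5.42 CPM against 12.6 ± 2.5 CPM. Egr1 (-0.04, adjusted p = 0.974) and Dusp6 (0.70, adjusted p = 0.223) did not pass. The 1 fall adjusted over the list alone was that of Fosb (-2.87). The list as a whole did not pass, with an adjusted p of 0.0516 by camera, 0.703 with an estimated correlation and 0.175 by fry. Of 25 cell cycle genes 1 rose, Mki67 (1.62, adjusted p = 0.0301, 4.45 ± 2.71 against 1.36 ± 0.224 CPM), and 2 did adjusted over the list alone. Ccnd1 had a log2 fold change of -0.33 (adjusted p = 0.483). The cell cycle list did not pass either, with an adjusted p of 0.11 by camera, 0.782 with an estimated correlation and 0.4 by fry. Etv5 lost its call without any single library other than Colo201 4R, and Mki67 without Colo201 4L, HCT116 1L, HCT116 1R or HCT116 3L.

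Of 23 tested genes of cholesterol synthesis and uptake 6 rose (Mvk, Mvd, Dhcr7, Srebf2, Hmgcs1, Fdps), 0 fell and 17 did not pass, and 19 rose adjusted over the list alone. Mevalonate kinase Mvk rose by 1.49 (SE 0.15, adjusted p = 0.00381) to 63.1 ± 17.6 from 21.9 ± 2.65 CPM, and Mvd by 1.41 (SE 0.14, adjusted p = 0.00429). The list passed camera with its preset correlation (adjusted p = 3.15e-09) and fry (adjusted p = 0.0269), but not camera with an estimated correlation (adjusted p = 0.67). Of 18 lipogenic genes 3 rose, Fads1 (0.42), Elovl6 (0.70) and Acly (0.58), and 5 did adjusted over the list alone, with adjusted p of 0.188 by camera and 0.0606 by fry. Of 21 genes of fatty acid oxidation and PPARA targets 5 fell, among them Acadm (-0.48), Ehhadh (-0.66) and Acaa1b (-0.73), and 7 did adjusted over the list alone; the list's adjusted p was 0.00446 by camera (0.0731 without Colo201 2R), 0.703 with an estimated correlation and 0.138 by fry.

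Of 21 tested xenobiotic metabolism genes 5 fell and 0 rose, or 11 and 1 adjusted over the list alone. Gsta2, a glutathione transferase, fell by 3.05 (SE 0.15, adjusted p = 0.000144), Cyp3a13 by 1.06, the P450 reductase Por by 0.87 and Cyp2e1, the most abundant of those that fell, by 0.55, from 9268 ± 675 to 6352 ± 735 CPM. Camera gave the list an adjusted p of 0.000987 (adjusted p = 0.67 with an estimated correlation), and fry 0.0248. Of the 6 lists that camera called between the lines with its preset correlation, 0 held with an estimated one. Fry, which asks whether the members move on balance 1 way, called 6, and its mixed form, which takes either direction, called 23 of 33. The Cyp2c and Gsta families hold near-identical members, so their single values are uncertain.

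**Figure D2:**
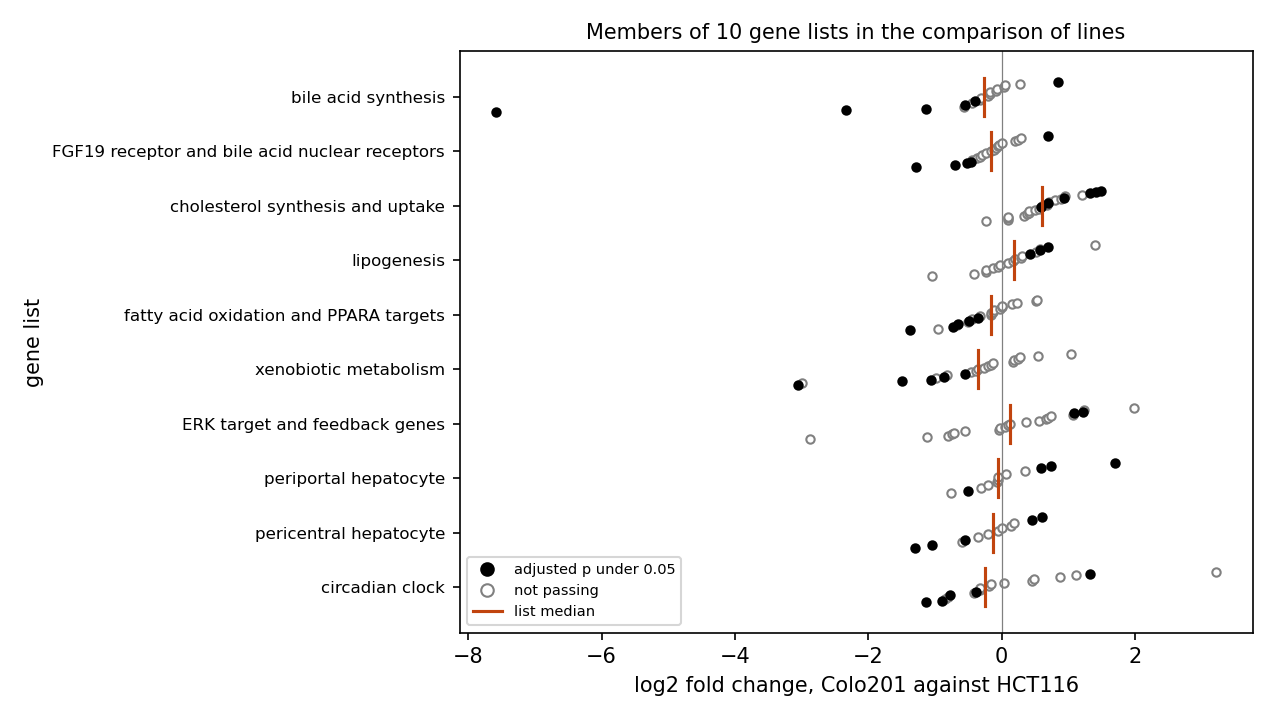
Log2 fold change, Colo201 against HCT116, of each tested member of 10 gene lists; filled points passed an adjusted p under 0.05 over all genes, open points did not, and the vertical bar is the list median. Of the cholesterol synthesis members 6 passed, all to the right of 0, and of the bile acid synthesis members 5 passed to the left and 1 to the right.

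Zonation markers moved in both directions. Among 12 periportal markers Cdh1 (1.70, SE 0.08, adjusted p = 0.000144), Gls2 (0.74) and Hal (0.59) rose and Pck1 (-0.50) fell; fry gave an adjusted p of 0.00936 for a rise while the list's median was -0.05 and its mean 0.12, and camera gave 0.493. Among 12 pericentral markers Cyp2e1, Glul (-1.04) and Slc1a2 (-1.30) fell and Lect2 (0.60) and Oat (0.46) rose, with adjusted p of 0.371 by camera and 0.0725 by fry. Of 12 general hepatocyte genes 3 rose, Apoa1 (0.47), Trf (0.51) and Ahsg (0.37). Of 8 fetal and oncofetal genes 1 rose, Dlk1, and 5 did adjusted over the list alone; Dlk1 had no count in any HCT116 library and was at least 9.34-fold higher in hosts of Colo201, at a mean of 0.449 CPM against a floor of 0.0481 CPM, 3 fragments over the group, for counting error only. That list passed camera (adjusted p = 0.000987; adjusted p = 0.337 with an estimated correlation) and fry (adjusted p = 0.00871).

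Of 18 clock genes 4 fell, among them Cry1 (-0.90), Nfil3 (-1.14) and Nr1d2 (-0.38), and Nr1d1 rose by 1.32 (SE 0.19, adjusted p = 0.0124); adjusted over the list alone 8 fell and 2 rose, and camera gave 0.245 and fry 0.252 for the list. The acute phase list of 26 had 1 rise, Lcn2 (1.77), and 1 fall, Orm2 (-1.47). In the unfolded protein and amino acid response list of 15, Trib3 (1.62) and Sdf2l1 (0.97) rose and Herpud1 (-0.53) fell. Psmb9 (0.92) was the 1 member of 18 interferon genes that passed. Of 14 hypoxia genes Ndrg1 (1.08) rose and Bnip3 (-0.41) fell, and of 15 genes of gluconeogenesis and amino acid catabolism 1 rose and 3 fell, the latter being Gpt2 (-0.43), Pck1 and Aass (-0.40). None of the 12 growth hormone and STAT5 genes passed.

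Few markers of other cells passed between the lines. No member passed in edgeR among 14 Kupffer cell and macrophage, 12 endothelial, 9 neutrophil and 5 lymphocyte markers or 13 mitochondrial mRNAs. Reln (0.89) passed among 13 stellate cell and matrix genes, Tfrc (-0.78) among 8 erythroid genes and Cela1 (1.23) among the 2 tested pancreatic genes, and 0 of 3 adipocyte genes did. Of 10 cholangiocyte markers Krt23 passed, with 18.5 ± 10.8 CPM in hosts of Colo201 against 1.12 ± 0.808 CPM. Colo201 4R had the highest mean log2 CPM of this list (2.51, against 0.22 to 1.10 in the others) and the lowest of the Kupffer cell (3.02, against 3.78 to 4.49), endothelial (4.25, against 4.43 to 5.03) and neutrophil lists (-3.02, against -2.61 to -0.92). It held Krt19 at 25.9 CPM where the other 7 libraries had 0.501 to 2.17 CPM, and Krt19 did not pass (adjusted p = 0.248). Without Colo201 4R the comparison of lines called 267 genes higher and 283 lower.

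By sex label, the comparison called fewer genes with 2 libraries against 2. Among libraries labelled male 18 genes were higher and 23 lower in hosts of Colo201, and among those labelled female 46 and 41. Cyp7a1 fell in both, by 6.62 (SE 0.84, adjusted p = 0.0396) in those labelled male and by 8.84 (SE 0.95, adjusted p = 0.0171) in those labelled female. Akr1c18, Cdh1 and Gsta2 also passed under both labels. The labels shared 24 called genes, 23 of them in the same direction, where 0.2 were expected from independent lists. The lists are not independent, since the same fit gave both contrasts a shared estimate of each gene's spread, which can raise the overlap. Across genes, which are not independent replicates, the log2 fold changes under the 2 labels correlated with a Spearman rho of 0.37. Among libraries labelled male the count was 22 without Colo201 2L, 13 without HCT116 1L, 2 without HCT116 1R and 21 without HCT116 3L or HCT116 3R. Among those labelled female it was 35 and 22 without Colo201 4L and 4R, and 19, 20, 41 and 20 without HCT116 1L, 1R, 3L and 3R.

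The difference between the lines depended on the sex label for 5 genes in edgeR. Of 17669 genes tested, 725 had an unadjusted p under 0.05, fewer than the share of 0.05 that chance alone gives. Cyp2b13 and Cyp2a4 are cytochromes P450 with female-biased expression in mouse liver. Both were higher in Colo201 among libraries labelled female, which expressed Y-linked genes and hardly any Xist. The rises there were 5.77 (SE 0.31, adjusted p = 0.00081) and 4.85 (SE 0.32, adjusted p = 0.00236) in edgeR, against 0.76 and 0.62 among libraries labelled male. Their interactions were 5.01 (SE 0.38, adjusted p = 0.0088) and 4.23 (SE 0.40, adjusted p = 0.0268). In the libraries labelled male Cyp2b13 stood at 240 to 424 CPM. Dnajc5, a co-chaperone, had an interaction of 2.73 (SE 0.18, adjusted p = 0.00673), with 23.8 and 25.3 CPM in Colo201 labelled male, 57.7 and 65.9 in Colo201 labelled female, 64.6 and 67.6 in HCT116 labelled male and 26.1 and 24.0 in HCT116 labelled female. Tnpo1, a nuclear import receptor, stood at 8.09 and 8.74 CPM in Colo201 labelled female and at 43.9 to 72.6 CPM elsewhere (interaction -2.59, SE 0.18, adjusted p = 0.00673). The fifth gene, Map4k5, had an interaction of -2.47 (SE 0.21, adjusted p = 0.0144). Each title number holds 1 combination of line and label, so these differences are also differences between numbers. In edgeR 0 genes passed without HCT116 1R, and 14, 13, 10 and 15 without Colo201 2R, 4L and 4R and HCT116 3L. Cyp2b13 and Cyp2a4 are near-identical to Cyp2b9 and Cyp2a5.

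**Figure D3:**
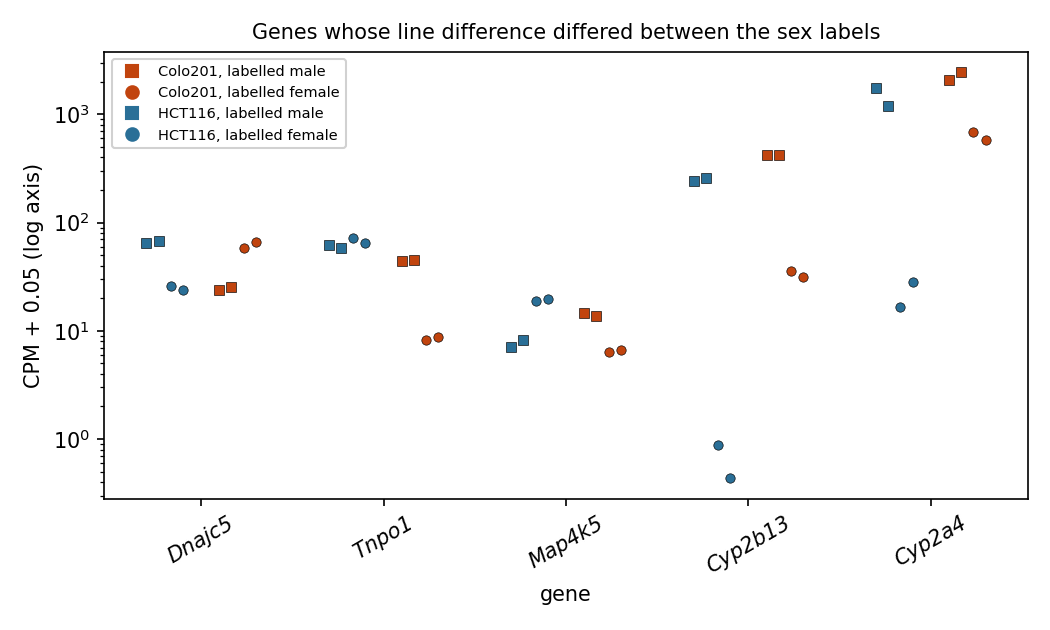
CPM (plus 0.05, log axis) of the 5 genes that passed the interaction, in the 8 libraries, with HCT116 at left and Colo201 at right of each gene, squares for libraries labelled male and circles for those labelled female. The 2 libraries of Colo201 labelled female hold 8.09 and 8.74 CPM of Tnpo1.

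The libraries labelled male were set against those labelled female to check the labels. Xist, the RNA that coats the inactive X chromosome of females, stood at 253 to 366 CPM in the 4 libraries labelled male and at 0.276 to 0.805 CPM in the 4 labelled female. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d reached at most 0.0742 CPM in the libraries labelled male and 9.06 to 63.5 CPM in those labelled female. Female-biased liver genes went the same way, with 24 of 27 higher in the libraries labelled male and 0 lower, led by Sult3a1 (9.75), Sult3a2 (9.54) and Slc22a26 (8.03), in log2 units, and 16 of 18 male-biased genes were lower there, among them Cyp4a12a (-9.62), C6 (-4.35) and Cyp2d9 (-3.05). In all, 346 genes were higher and 364 lower in the libraries labelled male by edgeR with line as a covariate. The female-biased list passed camera with the preset and with an estimated correlation (adjusted p = 0.0134), and the male-biased list with the preset only (adjusted p = 0.0704 with an estimated correlation). Summed by title number, 141 genes passed, and leaving out single libraries gave 355 and 469 without Colo201 2R and 4R and 327, 357, 398 and 416 without HCT116 1L, 1R, 3L and 3R.

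**Figure D4:**
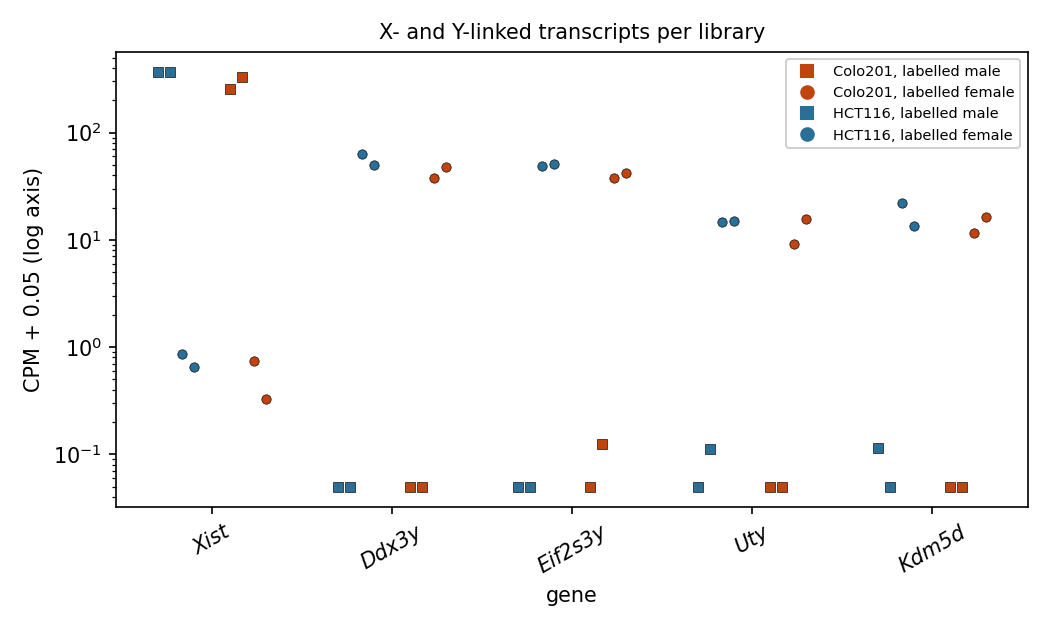
CPM (plus 0.05, log axis) of Xist and 4 Y-linked genes in the 8 libraries, with HCT116 at left and Colo201 at right of each gene, squares for libraries labelled male and circles for those labelled female. Squares hold Xist at 253 to 366 CPM, and circles hold each Y-linked gene at 9.06 to 63.5 CPM.

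Other lists also moved with the sex label. Of 20 major urinary protein genes, which male mouse liver expresses most, 9 were lower in the libraries labelled male and 18 were adjusted over the list alone (fry adjusted p = 0.00673; camera adjusted p = 0.232 with an estimated correlation). Between the lines 0 of these 20 passed and 2 rose adjusted over the list alone, although camera gave the list an adjusted p of 0.000987 (adjusted p = 0.703 with an estimated correlation; fry 0.261). The list's median log2 fold change between the lines was 5.57 in libraries labelled male and -0.02 in those labelled female, and its mean log2 CPM was 3.75 in Colo201 2L, -0.23 in Colo201 2R and -2.86 and -1.46 in HCT116 1L and 1R. Without Colo201 2L its adjusted p by camera was 0.0356. Of the 18 male-biased genes 1 fell in hosts of Colo201, Elovl3 (-2.06, adjusted p = 0.0483), and of the 27 female-biased genes Cyp17a1 rose (2.22) and Slc22a26 fell (-1.30). The 6 sex chromosome genes did not pass between the lines. Of 12 endothelial markers 5 were higher in the libraries labelled male, and all 12 were adjusted over the list alone (fry adjusted p = 0.0135, camera adjusted p = 0.277 with an estimated correlation). Of 14 Kupffer cell and macrophage markers 2 were higher there, and 11 adjusted over the list alone (fry adjusted p = 0.0604). The log2 fold change was positive for 8 of 9 neutrophil markers (fry adjusted p = 0.0279), but for only 3 of 10 cholangiocyte and 2 of 5 lymphocyte markers. The members of the Mup family share long stretches of sequence, so their single counts are uncertain.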

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

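The tests of exchanged or mixed samples, of separated clock genes, of paralogs, of title numbers, of Samd10 and of splits list by list were chosen only after the results were seen; the clock score and neighbour tests were restated before they were run, the latter with a looser limit. Regroupings of the 8 libraries into 4 and 4 were counted for 35 splits. The 845 genes of the comparison of lines, with sex label as covariate, were the highest count. The highest other was 340, in the split by sex label, which was fitted without a covariate, with at most 3 elsewhere. So 1 of 35 splits gave as many, the smallest share that 35 splits can give. That share cannot measure chance, even if the 8 libraries are independent. Because many genes differed between the sex labels, only splits balanced for sex label are comparable with the split by line. Those are too few for a share under 0.05. The 710 genes of the sex labels, with line as covariate, were likewise reached by 1 of 35. The same limit holds there for splits balanced for line. There the highest other was 155, in the split by line, which was fitted without a covariate. Libraries of a title number were the most alike, with a chi-square per gene of 15.62 to 31.6 against 39.85 to 125.21 in other pairs. As they also share line and sex label, this does not decide whether they are independent. Only 3 of the splits keep the title numbers whole, too few for a share under 0.05. The split by line gave 845 genes with sex label as covariate and 155 without. That by sex label gave 340 without a covariate and 710 with line as covariate. The remaining one gave 1 with sex label as covariate. With title numbers summed, edgeR called 0 genes higher and 3 lower between the lines (1719 and 1761 at an unadjusted p under 0.05; no other tool was run) and 141 between the sex labels. For the 6 gene lists called by camera with its preset correlation chance cannot be excluded, since 19 of 35 splits gave as many and the highest other was 15. List by list, the split by line had the smallest fry p of the 35 for 8 of 33 lists, among them bile acid synthesis, cholesterol synthesis, xenobiotic metabolism, fetal genes and FGF19 receptors, and the smallest camera p for 1, the FGF19 receptors. Fry does not compare members with other genes, so a split with many changed genes favours a small p in any list. The camera count is about what chance gives for 33 lists over 35 splits. So neither count adds support for a list.

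The sex labels and sex chromosome genes were opposite. In 8 of 8 libraries Xist and the 4 Y-linked genes opposed the label, which is consistent with labels exchanged between male and female animals. RNA of other animals or of the tumour added to the libraries labelled male would leave Y-linked reads in place, and the highest Y-linked value there was 0.0742 CPM. Whether the exchange lies in the labels alone or in the housing of the animals stays open.

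Cyp7a1 fell while clock genes shifted. The livers could have been collected at different times of day, which the labels do not give; with a score of the clock genes as covariate the log2 fold change of Cyp7a1 was -4.52 (SE 0.63, adjusted p = 0.314, edgeR) against -7.59 (SE 0.76) without it, and that of Cyp8b1 -3.38 (SE 0.47, adjusted p = 0.314) against -2.33 (SE 0.25). The call of Cyp7a1 ended although its unadjusted p was 0.00012, because edgeR with that covariate had 941 genes at an unadjusted p under 0.05 and 0 after adjustment (no other tool was run). Those 941 were near the share of 0.05 of 17669 tested genes that chance alone gives, against 3834 without the score. Before the test was run, a lost call had been set as the sign of collection time as the cause, and this was met. As no gene passed, the lost call is not particular to Cyp7a1. Collection time therefore stays open, a reading set after the value was seen. All 5 called clock genes separated the lines completely, as most called genes did, which decides nothing; without collection times in the labels, time and xenograft line, the biological difference in the design, cannot be told apart for them.

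The difference between lines depended on the sex label, by a test of the interaction, for Cyp2b13 (5.01), Cyp2a4 (4.23), Dnajc5 (2.73), Tnpo1 (-2.59) and Map4k5 (-2.47), in log2 units. The sums of the P450 genes with Cyp2b9 and Cyp2a5 rose by 3.87 and 1.21 in libraries labelled female. This argues only against a swap of reads with these paralogs at a constant total. Cyp2b9 itself rose there, from 33.3 and 10 CPM in HCT116 to 312 and 187 CPM in Colo201. Since Cyp2b9 itself rose, the sum would be higher even if reads counted as Cyp2b13 came from Cyp2b9, so the sum cannot decide. Cyp2b13 went from 0.836 and 0.384 CPM in HCT116 to 35.8 and 31.2 CPM in Colo201. That is a larger factor than for Cyp2b9, though from low values in HCT116. Shared reads stay open as a part of the rise of Cyp2b13. Cyp2a5 stood at 460 and 562 CPM in HCT116 and at 677 and 521 CPM in Colo201. Of Dnajc5, Tnpo1 and Map4k5, 1 had a neighbour within 50 kb with an opposite difference, Samd10 beside Dnajc5, and its change was 1.9% of that of Dnajc5 in CPM, which argues against exchanged reads. A difference between title numbers, such as cages, stays open: the largest difference between libraries of a number was 1.1 on the log2 scale, and number and combination of line and label cannot be told apart. Sex, as a biological difference, was not tested apart from the number.

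By camera with its preset correlation the lines also differed by sex label for cholesterol synthesis and uptake (adjusted p = 3.84e-08), major urinary proteins (6.77e-07), Kupffer cells and macrophages (0.00287), male-biased genes (0.00287), cholangiocytes (0.0252), mitochondrial mRNA (0.0252) and female-biased genes (0.0432). With an estimated correlation each had an adjusted p of 0.909. Single libraries stood apart in some of these lists. The mean log2 CPM of the Kupffer cell list was 3.02 in Colo201 4R and 3.86 in Colo201 4L, and that of the cholangiocyte list 2.51 and 1.04. For major urinary proteins it was 3.75 in Colo201 2L and -0.23 in Colo201 2R. Single libraries stood apart from the other 3 of their line for Ghr in Colo201 4R (442 CPM), S100a8 in Colo201 4R (0.146 CPM), Nfil3 in HCT116 3R (22.2 CPM) and Mup6 in HCT116 3R (0.167 CPM). These were 4 of 332 groups tested. The limit used would flag about 16.6, or 1 in 20, if each group held 4 independent values from a single normal population. Each group held 2 libraries of each sex label, and many genes differed between the labels. So 16.6 is not the number that chance gives here.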

How the results depend on the processing

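Counts divided by 4 and libraries summed by title number were chosen after seeing the data. Of 1843 values of 78 passing named genes under the alternatives, 1333 kept direction and call, 510 kept direction without passing and 0 reversed. The cause of each change below was not tested, except that stricter thresholds call fewer genes by construction. For genes higher and lower between lines (439 and 406), DESeq2 gave 883 and 920, an adjusted p under 0.01 gave 41 and 51, a 2-fold minimum 99 and 113, unfiltered FPKM 156 and 166, no sex covariate 88 and 67, summed title numbers 0 and 3, and single libraries left out 86 to 267 and 89 to 283. For the 41 genes in libraries labelled male, DESeq2 gave 529, the stricter p 0, FPKM with a pseudocount of 1 or 0.1 gave 27, unfiltered FPKM 11 and left-out libraries 2 to 53. For the 87 in those labelled female, DESeq2 gave 690, voom 142, the stricter p 10, unfiltered FPKM 26 and left-out libraries 19 to 79. For the 5 interaction genes, DESeq2 gave 58, the stricter p 3, FPKM 3, unfiltered FPKM 0 and left-out libraries 0 to 15. For the 710 genes between sex labels, DESeq2 gave 1483, the stricter p 225, a 2-fold minimum 338, unfiltered FPKM 462, no line covariate 340, summed title numbers 141 and left-out libraries 327 to 630. For the 6 lists, an estimated correlation gave 0, fry in either direction 23 and left-out libraries 5 to 10. A library left alone in its combination was assumed to vary like the others. Cyp7a1, Akr1c18, Mvk, Mvd, Spry4, Csad, Trib3 and Wnk4 had an adjusted p under 0.05 under every other scaling, tool and filter, without the sex covariate and without each library, but none of these 8 did with summed title numbers or with a clock score as covariate (summed, Cyp7a1 log2 fold change -7.57, adjusted p = 0.102). Depth limits low values: 4 counts were worth 0.0611 to 0.0652 CPM.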

Other observations

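Genes of mature and fetal liver below the threshold were also measured. Gpc3, an oncofetal proteoglycan, had a log2 fold change of 3.16 between the lines (adjusted p = 0.0643) and Afp one of 0.99 (adjusted p = 0.101), by edgeR. Epcam, a marker of cholangiocytes chosen after its values were seen, stood at 12.0 CPM in Colo201 4R and at up to 1.42 CPM in the other 7 libraries.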
